A study of Mus musculus with 6 samples.

How the data were processed

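RNA was sequenced from bone marrow macrophages of 2 genotypes, 3 libraries each, made with a SMARTER mRNA-seq kit per the labels' protocols. The table deposited by the authors held, per the file headers, estimated counts and FPKM values for each library and 55401 Ensembl genes, with symbols, positions, KEGG pathways and GO terms. The estimated counts were deposited by the authors as whole numbers without scaling for depth, as the file headers and the values show. The FPKM values were scaled by the authors for gene length and depth, per the file headers, and were 0.0001 wherever the count was 0. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counter, the annotation release and the use of strand in counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be separated. Of the gene IDs, 99.5% were also in GENCODE M21, on the same chromosome in each case, and 94.2% of the shared IDs had the same start and end. Positions are those of the deposited table.

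Low counts were not spread evenly: 44.6% of the values from 1 to 12 were 4, 8 or 12, against 25% for an even spread, and the best step was 3.74 counts (3.72 to 3.75). A sequenced fragment thus seemed to be worth about 3.74 counts and the libraries then hold 15766220 to 20526412 fragments. Counts treated as independent reads overstate precision, and the spread between libraries, not counting error, set the tests. Floors for genes at 0 were taken as 3 fragments over the group and cover counting error only. The 10 most abundant genes held 13.9% to 16.3% of each library. No pair of libraries lay within sampling noise: the chi-square per degree of freedom was 5.99 to 34.6 within genotypes and 53.6 to 84.9 between them, so none were merged as repeats of 1 library. This compares libraries with counting noise alone and does not show that they came from separate cultures.

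Counts were rounded to whole numbers, genes were filtered with filterByExpr by genotype and scaled with TMM factors (0.966 to 1.04), and genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 6 libraries entered the fit with genotype as the only term. The common biological coefficient of variation was 0.230. Gene lists with at least 5 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Exact two-sided permutation tests were run on log2 values of P2ry6 and Ldlr. KEGG and GO terms of 10 to 500 genes were tested by the hypergeometric distribution against tested genes with a term, immunoglobulin genes left out. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, tests of single values and plots.

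The test, the gene lists, the first set of other settings and the rule for named genes were fixed before the data were examined. The rule named P2ry6, Ldlr, Msr1, Cd36, Calr, Stim1, Orai1, Plcb2, Plcb3 and P2ry2. It added the 12 largest rises and 12 largest falls among called genes with separated libraries and a mean of at least 5 CPM in 1 or both genotypes, leaving out predicted genes. From each list it took up to 4 members with the smallest unadjusted p. Because the 12 falls were all immunoglobulin segments, the 12 largest falls outside the immunoglobulin genes and Jchain were added after the values were seen. The plasma cell genes and the genes of the enrichment analysis were also added then.

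The procedure was tested on simulated data with the means and library sizes of these libraries and 200 changed genes among 17690 tested, for the comparison of double with single knockout. It recovered 22.4% of genes changed 1.5-fold, 71.2% of those changed 2-fold and 79.0% of those changed 4-fold. Among genes at 5 CPM or more the shares were 45.5%, 91.8% and 100%. Of the calls 1.54% were on unchanged genes. The planted list was found, and 1 of the other lists was called as well. Genes were drawn independently, with a dispersion that followed the trend with level. The simulation therefore held neither correlation between genes nor a dispersion particular to each gene. It does not test how list calls behave where genes vary together.

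The first set of other settings comprised RLE factors, library totals alone, no filter on low counts, a minimum mean of 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, a test against a 1.5-fold change and libraries thinned to the smallest total. After the data were seen, counts per fragment, immunoglobulin genes (with Jchain) left out, offsets for GC content and limma on log2(FPKM + 1) for genes at 1 or above in 3 libraries were added. Of the deposited values 0 per-sample columns were left unused.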

Results

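RNA sequencing was carried out on bone marrow macrophages from mice lacking the low-density lipoprotein receptor gene Ldlr (single knockout) and from mice lacking both Ldlr and P2ry6, the gene of the UDP-sensing P2Y6 receptor (double knockout). All cultures had received oxidised LDL at 50 µg/ml 7 days after confluence, a treatment that turns macrophages into lipid-filled foam cells. Each genotype was represented by 3 libraries, and no culture without oxidised LDL was analysed here. The series description speaks of 4 macrophages while 6 samples were listed, so what the 3 libraries of a genotype stand for is not settled. The estimated counts summed to 58965664, 76768781 and 74856652 in single knockout replicates 1 to 3. The totals were 71097614, 69075644 and 63435403 in double knockout replicates 1 to 3. Low values lay on a step of 3.74 counts, so that a fragment appeared to be worth about 3.74 counts. Levels are given as CPM, counts scaled to library size with TMM factors, mean ± SD over 3 libraries (n = 3 per genotype). Adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The labels do not say that replicates came from separate animals or cultures, so these p values measure only the spread between the libraries, which may be technical.

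The first comparison asked whether the genes named in the genotypes differed in transcript level as the labels say. P2ry6 (ENSMUSG00000048779, chromosome 7, 100937630 to 100974649, minus strand, GRCm38) fell from 63.2 ± 0.209 to 7.099 ± 0.2995 CPM, which left 11.2% of the single knockout level. Its counts were 3635, 4710 and 4582 in the single knockout libraries and 539, 495 and 454 in the double knockout libraries. Ldlr (ENSMUSG00000032193, chromosome 9, 21723483 to 21749919, plus strand), which both genotypes lack, was at 16.8 ± 4.31 CPM in the single and 14.2 ± 2.403 CPM in the double knockout. The log2 fold change of P2ry6 was -3.15 (SE 0.06, adjusted p = 1.03e-06), and that of Ldlr was -0.24 (SE 0.21, adjusted p = 0.555), smaller than the spread between replicates. An exact two-sided permutation test of the P2ry6 log2 values gave p = 0.1, the smallest value that 3 libraries against 3 allow. The table gives whole-gene values, so neither the position of the remaining P2ry6 reads nor the state of the Ldlr exons was examined.

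The second comparison asked which genes differed between foam cells with and without P2ry6. Among genes of at least 5 CPM with separated libraries, predicted genes left out, the largest rises in the double knockout were those of Arhgef17 and C5ar1. Arhgef17 is a Rho guanine nucleotide exchange factor gene that lies next to P2ry6, and C5ar1 is the gene of the receptor for the complement fragment C5a. Arhgef17 went from 17.8 ± 3.15 to 194 ± 4.72 CPM and C5ar1 from 25.2 ± 1.396 to 272 ± 8.58 CPM. The largest falls were those of immunoglobulin variable segments. Outside the immunoglobulin loci the falls included the betaine and GABA transporter gene Slc6a12, the pattern recognition molecule gene Ptx3 and the gelatinase gene Mmp9. Of 24 genes induced by type I interferon 17 were higher in the double knockout, as were the C1q subunit genes C1qa and C1qb. Of 20 glycolysis and hypoxia genes 11 were lower, as were 5 of 11 MHC class II and costimulation genes. These 3 lists passed camera with a preset correlation but not with one estimated from these libraries (adjusted p = 0.136 for each with an estimated correlation).

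Of 18199 genes tested, 1774 passed an adjusted p of 0.05, 674 higher and 1100 lower in the double knockout. Of the 1774, 1526 were protein coding (608 higher, 918 lower), and 145 belonged to the immunoglobulin genes and Jchain (1 higher, 144 lower). Without the 169 tested genes of that group, Jchain included, 673 genes were higher and 956 lower. Of all tested genes, 207 higher and 328 lower genes differed by at least 2-fold. The libraries of both genotypes did not overlap for 32.1% of the tested genes, where chance gives 10%. The balance of directions depended on scaling: 38.0% of the called genes were higher with TMM factors, whereas 62.3% of the 2058 genes called with library totals alone were higher. Leaving out 1 library lowered the number of called genes by over 1.5 times for every library except single knockout replicate 2: 938 without single knockout replicate 1, 912 without single knockout replicate 3, and 1076, 808 and 833 without double knockout replicates 1, 2 and 3.

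**Figure D1:**
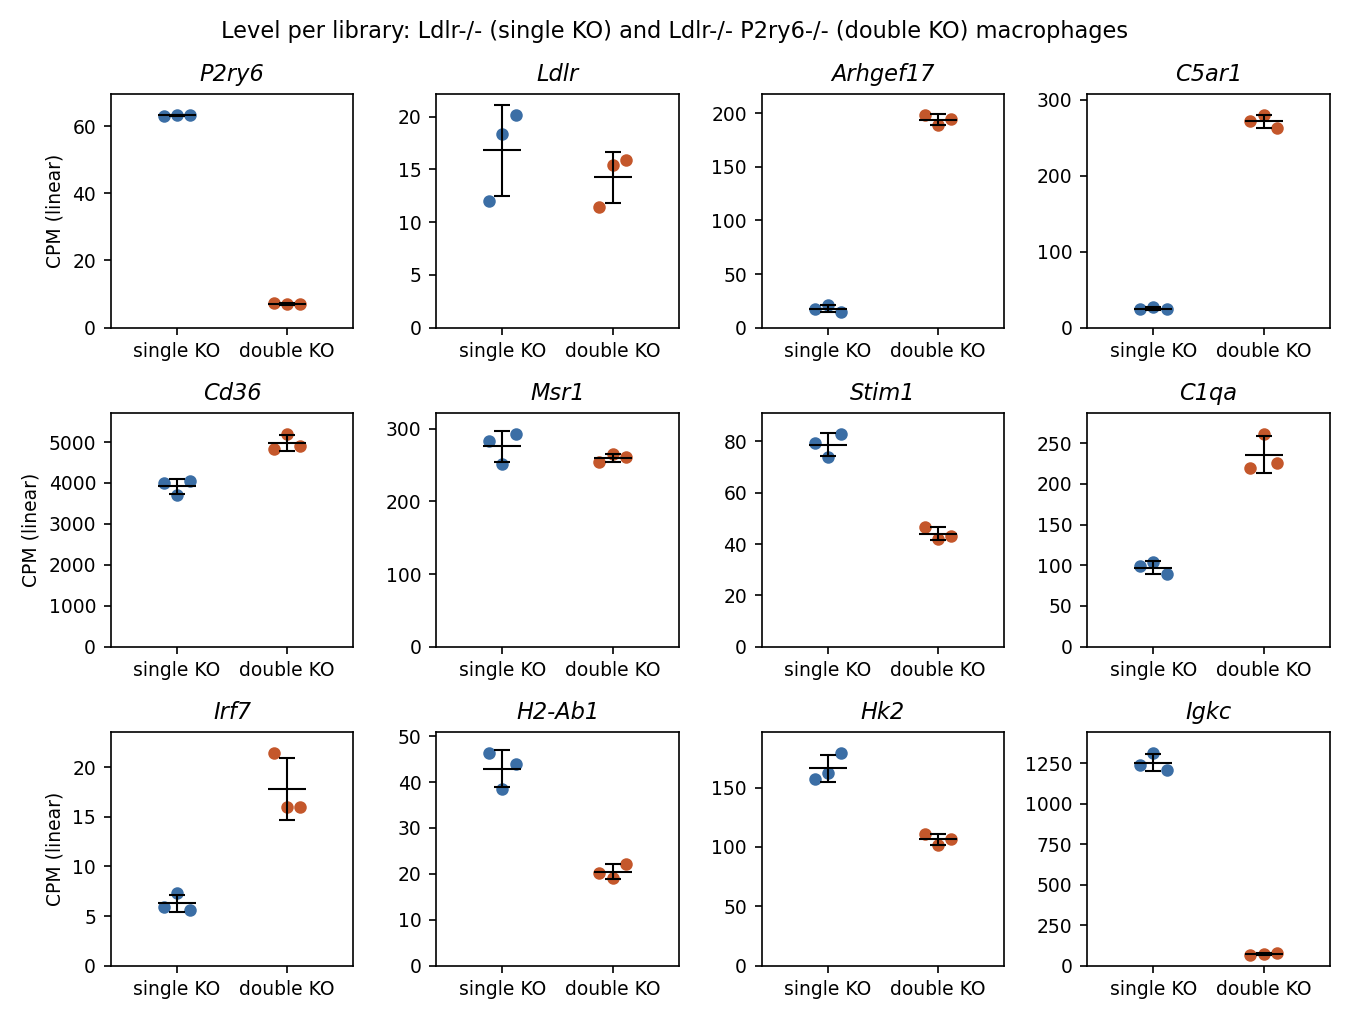
Level in CPM (linear axes from 0) of 12 genes in each library; points are the 3 libraries of a genotype, horizontal marks the mean and bars the SD. The 3 double knockout libraries lay below all 3 single knockout libraries for P2ry6, Stim1, H2-Ab1, Hk2 and Igkc and above them for Arhgef17, C5ar1, Cd36, C1qa and Irf7, while Ldlr and Msr1 overlapped.

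With predicted genes left out, the 12 largest rises among genes of at least 5 CPM with separated libraries were Arhgef17, C5ar1, Cyp4b1, Robo4, Ccl8, Adgrl4, Angpt2, Emcn, Cdh5, Pgf, Car6 and Oasl1. The predicted gene Gm12715, left out by that rule, rose from 12.4 ± 0.469 to 122 ± 36.2 CPM (log2 fold change 3.31, adjusted p = 5.13e-04). C5ar1 (ENSMUSG00000049130, chromosome 7, 16246743 to 16259540) had a log2 fold change of 3.43 (SE 0.06, adjusted p = 1.03e-06), and Arhgef17 (ENSMUSG00000032875, chromosome 7, 100869752 to 100932107) one of 3.45 (SE 0.13, adjusted p = 2.80e-05). The chemokine gene Ccl8 rose from 0.859 ± 0.257 to 6.27 ± 1.65 CPM. Several of the others are best known from blood vessels. The endothelial guidance receptor gene Robo4 rose from 0.923 ± 0.702 to 8.16 ± 0.841 CPM and the adhesion receptor gene Adgrl4 from 1.74 ± 1.19 to 11.3 ± 0.916 CPM. The angiopoietin gene Angpt2 rose from 4.77 ± 1.93 to 26.98 ± 3.02 CPM, the placental growth factor gene Pgf from 2.61 ± 1.19 to 10.9 ± 0.477 CPM, and the VE-cadherin gene Cdh5 from 4.34 ± 2.78 to 18.2 ± 1.53 CPM. Cyp4b1 rose from 0.778 ± 0.683 to 7.32 ± 0.823 CPM, the endomucin gene Emcn from 1.05 ± 0.735 to 5.64 ± 0.956 CPM, and the carbonic anhydrase gene Car6 from 3.72 ± 1.72 to 14.1 ± 2.69 CPM. Among the single knockout libraries Robo4, Adgrl4, Angpt2, Pgf, Cdh5 and Emcn were each highest in replicate 2, Cdh5 at 7.51 CPM against 3.19 and 2.31 CPM in replicates 1 and 3. All but 4 of these 12 calls held in each of the 6 fits that left out 1 library. The exceptions were Cyp4b1 (highest adjusted p 0.0742, without single knockout replicate 1), Emcn (0.0978, without single knockout replicate 3), Cdh5 (0.0868, without single knockout replicate 1) and Car6 (0.0615, without single knockout replicate 1).

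The 12 largest falls were all immunoglobulin variable segments: Igkv6-25, Igkv3-9, Igkv4-58, Ighv5-17, Ighv1-78, Igkv3-12, Igkv5-48, Igkv4-72, Ighv2-9-1, Igkv6-32, Ighv1-69 and Igkv3-2. Igkv6-25 (chromosome 6, 70215400 to 70215957) was at 9.36 ± 0.464 CPM in the single knockout and at 0 in all double knockout libraries, at least 170-fold lower against a floor of 3 fragments over the group. Igkv3-9 (chromosome 6, 70588189 to 70588777) was at 6.66 ± 1.11 CPM and at 0, at least 121-fold lower. Ighv5-17 went from 22.2 ± 1.06 to 0.04604 ± 0.0797 CPM and Igkv3-2 from 20.98 ± 1.31 to 0.357 ± 0.199 CPM. Summed over the 169 tested genes of the immunoglobulin set, which includes Jchain, the level was 4491 ± 221 CPM in the single and 281 ± 26.3 CPM in the double knockout. Among constant regions, chosen after their values were seen, Igkc fell 17.1-fold, Igha 29.3-fold and Ighg2b 19.1-fold. Ighg2c, Ighg1 and Iglc1 fell 26.6-fold, 23.2-fold and 14.5-fold, and Iglc2 and Ighg3 fell less, 9.01-fold and 3.31-fold. Jchain, which links antibody units, fell 20.5-fold. Ighm was at 40.2 ± 1.795 and 46.1 ± 3.46 CPM (adjusted p = 0.156). Variable segments resemble one another closely, and the counting method is not given in the sources used here, so the value of a single segment is uncertain.

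With the immunoglobulin genes and Jchain left out, the 12 largest falls by the same rule, a selection made after the values were seen, were those of Hba-a1, P2ry6, Snca, mt-Atp6, Slc6a12, Ptx3, Sfrp2, Mmp9, Aldh1a2, Rspo2, Fignl1 and Rasd2. Slc6a12 (chromosome 6, 121343076 to 121365372) fell from 114 ± 14.7 to 22.2 ± 3.17 CPM (adjusted p = 2.30e-04) and Ptx3 (chromosome 3, 66219910 to 66225805) from 47.3 ± 2.43 to 9.396 ± 1.16 CPM (adjusted p = 6.67e-05). The Wnt pathway genes Sfrp2 and Rspo2 fell from 10.9 ± 0.494 to 2.203 ± 0.418 CPM and from 16.4 ± 0.832 to 3.77 ± 0.519 CPM, and the retinoic acid synthesis gene Aldh1a2 from 22.5 ± 0.734 to 4.95 ± 1.46 CPM. mt-Atp6 fell 5.598-fold, but its annotated span overlaps that of mt-Atp8, so reads of the overlap cannot be assigned with certainty. mt-Atp8 was not higher in the double knockout (873 ± 249 CPM in the single and 574 ± 27.9 CPM in the double knockout). This argues against reads moved to mt-Atp8 as the cause of the fall of mt-Atp6. The haemoglobin gene Hba-a1 varied from 2.47 to 17.7 CPM among single knockout libraries, and its near-identical copy Hba-a2 makes it uncertain. Hba-a1 and Fignl1 lost their call in some of the fits that left out 1 library (highest adjusted p 0.1199 and 0.106, both without double knockout replicate 3), and P2ry6 and the other 9 did not.

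The third comparison asked which of 39 gene lists, fixed before the data were examined, moved between genotypes, chosen for foam cell biology, P2Y6 receptor signalling and other cell types of bone marrow. Of 34 tested lists 11 passed camera with a preset correlation of 0.01, 6 as higher and 5 as lower in the double knockout, but 0 passed when the correlation was estimated from these 6 libraries (4 had an unadjusted p under 0.05). In the 6 lists that passed as higher, the members called higher were 17 of 24 for the type I interferon response, 6 of 15 for complement and apoptotic cell uptake, 5 of 19 for ER chaperones, 4 of 12 for chemoattractant receptors, 2 of 30 for the cell cycle and 1 of 6 for T and NK cells. In the 5 that passed as lower, the members called lower were 11 of 20 for glycolysis and hypoxia, 5 of 11 for MHC class II and costimulation, 2 of 6 for osteoclasts, 2 of 7 for B cells and 1 of 5 for erythroid cells. A total of 15 passed fry, which tests whether the genes of a list move on balance in one direction without comparing them with other genes. Of these 15, 9 also passed camera, and the ER chaperone and cell cycle lists passed camera alone. The remaining 5 lists had fewer than 5 measured members and were not tested.

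**Figure D2:**
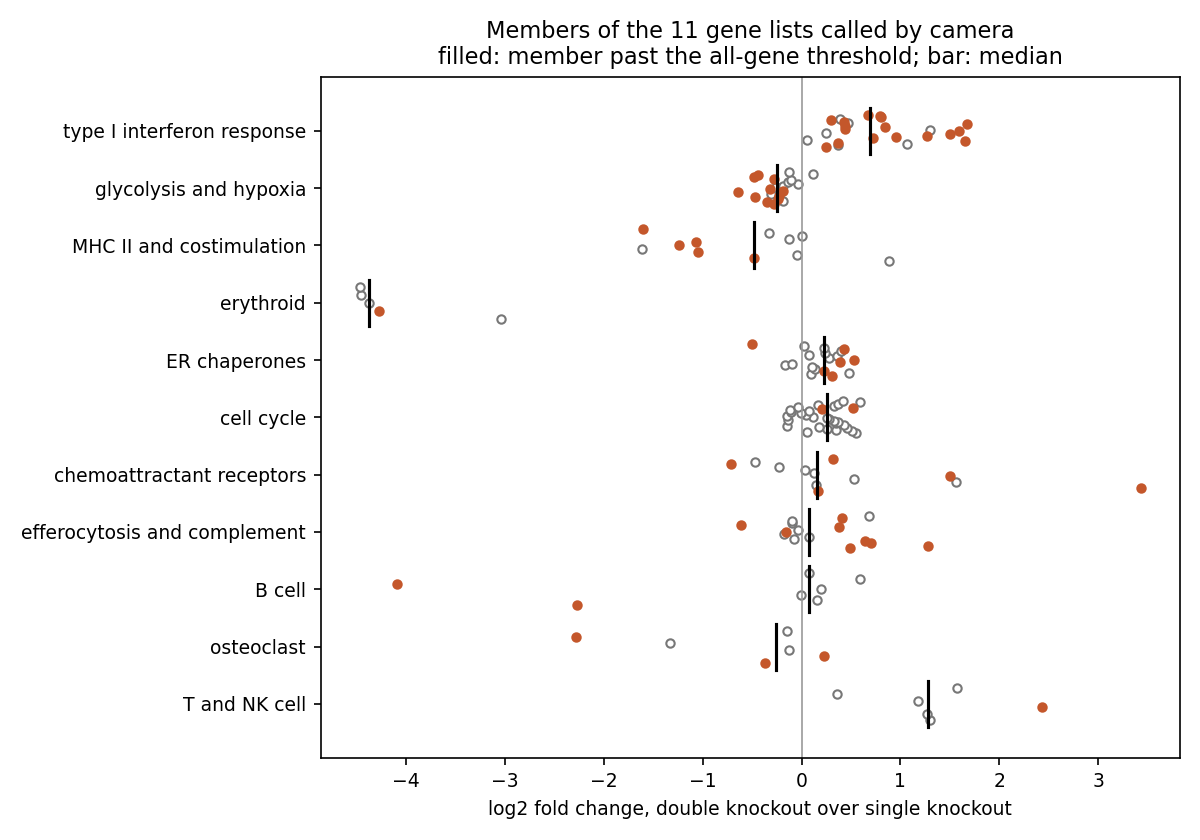
Log2 fold change (double over single knockout, horizontal axis) of each measured member of the 11 gene lists called by camera; filled points are members past the all-gene threshold, open points the others, and bars the list medians. Interferon genes lay above 0 throughout, erythroid genes below it, and most glycolysis genes below it.

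In the type I interferon list, 17 of 24 measured genes rose and 0 fell over all genes tested, and 17 rose with p values adjusted over the list alone. The list passed camera (adjusted p = 2.66e-14; adjusted p = 0.136 with an estimated correlation), and its median log2 fold change was 0.70. Irf7, the transcription factor that amplifies interferon production, rose from 6.28 ± 0.885 to 17.8 ± 3.15 CPM, Oasl1 from 3.87 ± 0.459 to 12.4 ± 1.34 CPM, Ifit3 from 3.17 ± 0.4098 to 7.65 ± 1.17 CPM and Oas2 from 13.6 ± 1.19 to 24.4 ± 3.14 CPM. The calls of these 4 genes held in each of the 6 fits that left out 1 library. Oas and Ifit genes have close relatives in the genome, so the split of reads among them is uncertain.

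In the glycolysis and hypoxia list, 11 of 20 genes fell and 0 rose (adjusted over the list alone, 14 fell and 1 rose), with a median log2 fold change of -0.25 (camera adjusted p = 1.88e-06; adjusted p = 0.136 with an estimated correlation). Hk2, a hexokinase gene, fell from 166 ± 11.5 to 106 ± 4.43 CPM and the glucose transporter gene Slc2a1 from 166 ± 7.57 to 123 ± 2.58 CPM. The lactate exporter gene Slc16a3 fell from 104 ± 3.298 to 75.1 ± 2.36 CPM and the pyruvate kinase gene Pkm from 4053 ± 27.6 to 3346 ± 125 CPM. In the oxidative phosphorylation list 2 of 23 genes rose and 0 fell (adjusted over the list alone, 3 and 0), and the list did not pass (adjusted p = 0.212). Fatty acid oxidation and PPAR genes gave 3 rises and 2 falls among 16 (adjusted over the list alone, 4 and 2; camera adjusted p = 0.448). Pparg rose from 28.4 ± 1.02 to 37.9 ± 0.488 CPM and Acadl fell from 233 ± 9.06 to 188 ± 4.11 CPM.

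MHC class II and costimulation genes fell in 5 of 11 cases and rose in 0 (adjusted over the list alone, 6 fell and 1 rose), with a camera adjusted p of 1.07e-05 and an adjusted p = 0.136 with an estimated correlation. H2-Ab1 fell from 42.9 ± 4.03 to 20.5 ± 1.62 CPM, H2-Aa from 44.5 ± 8.697 to 18.8 ± 0.504 CPM, H2-Eb1 from 16.4 ± 2.05 to 5.42 ± 1.21 CPM and the costimulatory ligand gene Cd86 from 14.9 ± 1.01 to 7.22 ± 0.214 CPM. B cells also use some of these genes. Antibody transcripts, summed with Jchain, fell in the same libraries, from 4491 to 281 CPM. Of 7 genes of the B cell list 2 fell and 0 rose, with Ighm at 40.2 CPM in the single and 46.1 CPM in the double knockout. Whether other cells account for the falls of MHC class II genes was not tested.

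Complement and apoptotic cell uptake genes gave 6 rises and 2 falls among 15 (adjusted over the list alone, 7 and 3). The camera test gave an adjusted p of 0.0165, against adjusted p = 0.313 with an estimated correlation. The C1q subunit genes C1qa and C1qb rose from 97.2 ± 7.73 to 236 ± 22.5 CPM and from 443 ± 29.9 to 721 ± 42.3 CPM. The apoptotic cell receptor gene Axl rose from 208 ± 11.2 to 292 ± 12.2 CPM, while Mfge8, whose product bridges phagocytes to dying cells, fell from 520.4 ± 17.9 to 339.9 ± 2.91 CPM. Chemoattractant receptor genes gave 4 rises and 1 fall among 12 (adjusted over the list alone, 5 and 2). The camera test gave an adjusted p of 0.00887, against adjusted p = 0.442 with an estimated correlation. Beside C5ar1, the chemokine receptor gene Ccr5 rose from 15.6 ± 3.33 to 44.1 ± 6.93 CPM, and the formyl peptide receptor gene Fpr1 fell from 25.9 ± 1.03 to 15.8 ± 1.87 CPM. Both list calls ended without single knockout replicate 2 (adjusted p = 0.0739 and 0.101) and without double knockout replicate 1 (adjusted p = 0.07102 for each).

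ER chaperone genes gave 5 rises and 1 fall among 19 (adjusted over the list alone, 12 and 2). The camera test gave an adjusted p of 0.00487, against adjusted p = 0.558 with an estimated correlation. The calcium-binding chaperone gene Calr rose from 881 ± 58.4 to 1090.4 ± 60.3 CPM (adjusted p = 0.0258) and Hspa5 from 717 ± 95.6 to 1037 ± 69.6 CPM (adjusted p = 0.0198). By contrast Xbp1, a transcription factor gene of the unfolded protein response that plasma cells also express strongly, fell from 74.3 ± 3.58 to 52.7 ± 2.86 CPM. Calr and Hspa5 each lost their call in 4 of the 6 fits that left out 1 library (highest adjusted p 0.090 and 0.07301, both without double knockout replicate 2). Cell cycle genes gave 2 rises and 0 falls among 30 (adjusted over the list alone, 3 and 0). The camera adjusted p was 0.00489, against adjusted p = 0.668 with an estimated correlation, and the call ended without single knockout replicate 3 (adjusted p = 0.0647). Among the single knockout libraries, replicate 2 was highest for 28 of the 30 cell cycle genes and for 16 of the 19 ER chaperone genes. The cell cycle genes with calls were Pcna, up from 278 ± 0.548 to 322 ± 17.7 CPM, and the mitotic kinase gene Plk1, up from 13.2 ± 1.6 to 18.96 ± 1.91 CPM. Each lost its call in 5 of the 6 fits that left out 1 library (highest adjusted p 0.124 for Pcna, without double knockout replicate 3, and 0.127 for Plk1, without double knockout replicate 2).

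Genes for uptake of modified LDL did not pass camera (1 rise and 2 falls among 13, the same adjusted over the list alone; camera adjusted p = 0.212), while fry gave them as lower (adjusted p = 0.0373). The scavenger receptor gene Cd36 (chromosome 5, 17781690 to 17888801) rose from 3916 ± 185 to 4976 ± 198 CPM (log2 fold change 0.35, SE 0.05, adjusted p = 0.00557), and Marco fell from 128 ± 10.8 to 60.1 ± 4.49 CPM. Msr1, the gene of scavenger receptor A (chromosome 8, 39581685 to 39642673), was at 276 ± 21.6 and 260.2 ± 5.49 CPM, with a log2 fold change of -0.08 (95% interval -0.25 to 0.09, adjusted p = 0.463). Lrp1 fell from 3594 ± 119 to 2829 ± 240.4 CPM, a call lost in 3 of the 6 fits that left out 1 library (highest adjusted p 0.0761, without double knockout replicate 3). Cholesterol efflux genes regulated by LXR gave 1 rise and 1 fall among 15 (adjusted over the list alone, 4 and 3; camera adjusted p = 0.943). Cholesterol synthesis genes gave 0 rises and 2 falls among 22 (the same adjusted over the list alone; adjusted p = 0.344), and lipid droplet genes 2 rises and 1 fall among 18 (adjusted over the list alone, 4 and 3; adjusted p = 0.982). Srebf2, the regulator of sterol synthesis, fell from 90.4 ± 5.33 to 69.2 ± 0.675 CPM, the fatty acid carrier gene Fabp4 rose from 301 ± 15.7 to 392 ± 6.81 CPM, and Hilpda fell from 50.7 ± 3.35 to 33.1 ± 1.71 CPM.

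Of the genes of store-operated calcium entry, 4 of 12 fell and 0 rose, the same with p values adjusted over the list alone, but the list did not pass camera (adjusted p = 0.07999) and passed fry as lower (adjusted p = 0.0153). Stim1, the calcium sensor of the ER (chromosome 7, 102267806 to 102437319), fell from 78.8 ± 4.599 to 43.96 ± 2.53 CPM (log2 fold change -0.84, SE 0.07, adjusted p = 7.70e-04). The channel gene Orai1 was at 27.2 ± 3.35 and 21.1 ± 6.91 CPM (adjusted p = 0.4203). The call of Stim1 held in each of the 6 fits that left out 1 library. Those of Atp2a3, Saraf and Cracr2a were lost in 6, 5 and 4 of these fits. Their highest adjusted p values were 0.106, 0.0883 and 0.0687, each without double knockout replicate 2. Stim1 lies 1.29 Mb from P2ry6 on the same chromosome. Genes of Gq and phospholipase C signalling gave 1 rise and 4 falls among 14 (adjusted over the list alone, 2 and 6; camera adjusted p = 0.0982; fry adjusted p = 0.0236, as lower). The protein kinase C gene Prkcb fell from 165 ± 11 to 109 ± 3.91 CPM and the inositol trisphosphate receptor gene Itpr2 from 62.6 ± 2.19 to 44.2 ± 2.83 CPM. The phospholipase genes Plcb2 (67.6 ± 2.52 and 61.7 ± 2.29 CPM) and Plcb3 (69.3 ± 2.496 and 67.9 ± 1.52 CPM) did not pass. Purinergic receptor and nucleotidase genes other than P2ry6 gave 1 rise and 2 falls among 18 (the same adjusted over the list alone; adjusted p = 0.837). P2ry1 fell from 17.7 ± 0.905 to 10.2 ± 0.418 CPM, and P2ry2, the neighbour of P2ry6 on the other side from Arhgef17, was at 32.4 ± 20.3 and 13.3 ± 2.81 CPM (adjusted p = 0.103).

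**Figure D3:**
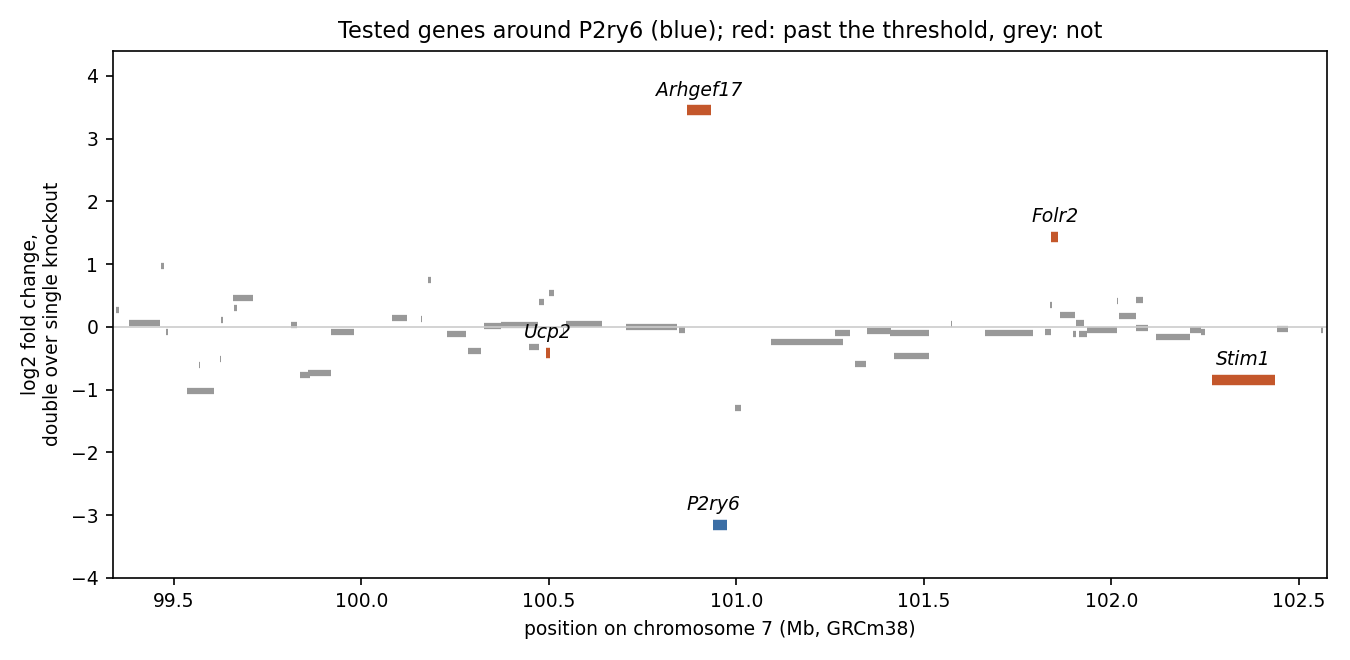
Log2 fold change (double over single knockout, vertical axis) of tested genes against their position on chromosome 7 (horizontal axis, Mb, GRCm38) within 1.6 Mb of P2ry6; each bar spans a gene, blue for P2ry6, red for other genes past the threshold and grey for the rest. Arhgef17 rose and P2ry6 fell, and Folr2, Stim1 and Ucp2 were the other called genes of the window.

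Inflammatory genes moved in both directions. Cytokine and chemokine genes of the NF-κB list gave 5 rises and 3 falls among 19 (the same adjusted over the list alone; camera adjusted p = 0.617). Ccl3 fell from 73.3 ± 5.88 to 48.5 ± 1.63 CPM, Cxcl3 fell from 3.701 ± 0.912 to 1.09 ± 0.0884 CPM and the interleukin gene Il1a rose from 7.16 ± 0.881 to 11.97 ± 0.765 CPM. Il1a lost its call in 1 of the 6 fits that left out 1 library, the one without double knockout replicate 2 (adjusted p = 0.0562). In the inflammasome list 0 of 10 genes passed over all genes or adjusted over the list alone (adjusted p = 0.982; fry adjusted p = 0.851). Of these 10 genes 3 had an unadjusted p under 0.05 and DESeq2 called 3. The sensor gene Nlrp3 was at 7.39 ± 1.703 and 4.899 ± 1.43 CPM. Alternative activation genes gave 4 rises and 2 falls among 12 (the same adjusted over the list alone; adjusted p = 0.598); the median log2 fold change was 0.42 and the mean -0.04. Tgm2 rose from 144 ± 4.37 to 191 ± 12.4 CPM and Irf4, which plasma cells also express, fell from 3.65 ± 0.478 to 0.574 ± 0.162 CPM. Among 12 immediate early genes 2 rose and 2 fell (adjusted over the list alone, 3 and 4; camera adjusted p = 0.617). Junb fell from 92.1 ± 0.426 to 55.5 ± 2.23 CPM. For that list fry passed in the direction of lower (adjusted p = 0.0178), the direction camera gave without a call, while the median log2 fold change was 0.05 and the mean 0.04.

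Macrophage identity genes also split, with 4 rises and 5 falls among 14 (adjusted over the list alone, 4 and 8; camera adjusted p = 0.141; fry adjusted p = 0.00947, as lower). The lysozyme gene Lyz2 fell from 11868 ± 665 to 6858 ± 193 CPM, the LPS co-receptor gene Cd14 from 60.7 ± 4.88 to 28.8 ± 0.435 CPM and Cd33 from 92.6 ± 6.46 to 41.5 ± 0.747 CPM. The transcription factor gene Mafb rose from 118 ± 3.22 to 172 ± 5.47 CPM. Of the genes of lipid-associated macrophages, 2 of 14 rose and 2 fell (adjusted over the list alone, 5 and 3; adjusted p = 0.974). Spp1 rose from 2901 ± 110.3 to 3836 ± 203 CPM and Gpnmb fell from 25549.8 ± 1129 to 19978 ± 88.3 CPM. Lysosome and autophagy genes gave 2 rises and 3 falls among 25 (adjusted over the list alone, 2 and 4; adjusted p = 0.982), and the protease genes Lgmn and Ctsl rose from 1432 ± 28.6 to 2079 ± 84.9 CPM and from 1052 ± 63.4 to 1583 ± 76.2 CPM. Matrix and protease genes gave 4 rises and 3 falls among 18 (adjusted over the list alone, 11 and 5; adjusted p = 0.386; median log2 fold change 0.18, mean -0.05). Mmp8 fell from 99.3 ± 17.8 to 27.2 ± 2.03 CPM, Mmp9 fell from 11.3 ± 2.29 to 2.32 ± 0.123 CPM and Mmp2 rose from 54.8 ± 2.25 to 85.6 ± 3.87 CPM.

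The antioxidant, integrated stress response, heat shock and p53 lists passed neither camera nor fry. Of the NRF2 antioxidant genes, 0 of 16 rose and 3 fell (adjusted over the list alone, 0 and 6; camera adjusted p = 0.138), the largest change being that of the cystine transporter gene Slc7a11, from 634 ± 65.9 to 270.1 ± 13.8 CPM. The integrated stress response list gave 3 rises and 2 falls among 15 (adjusted over the list alone, 3 and 4; adjusted p = 0.982). Aldh1l2 rose from 22.2 ± 4.97 to 45.1 ± 3.82 CPM. The call of Aldh1l2 ended without double knockout replicate 2 (adjusted p = 0.0512). Heat shock genes gave 2 rises and 0 falls among 10 (the same adjusted over the list alone; adjusted p = 0.344), the mitochondrial chaperone gene Hspd1 rising from 277 ± 9.296 to 351 ± 5.48 CPM. Of 12 p53 target genes, 0 passed over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05 and DESeq2 called 1 (camera adjusted p = 0.837; fry adjusted p = 0.30).

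Transcripts of other cell types were measured in the same libraries. In the B cell list 2 of 7 genes fell and 0 rose, the same adjusted over the list alone: Igkc and Cd79a, the latter from 1.52 ± 0.447 to 0.312 ± 0.133 CPM. Cd79b was at 7.72 ± 0.966 and 8.62 ± 0.373 CPM. The call of Cd79a was lost in 4 of the 6 fits that left out 1 library (highest adjusted p 0.0716, without single knockout replicate 1). The list passed as lower (adjusted p = 0.0374; adjusted p = 0.558 with an estimated correlation) although its median log2 fold change was 0.07 and its mean -0.77. This call ended without single knockout replicate 2 (adjusted p = 0.258) and without double knockout replicate 1 (adjusted p = 0.101). Erythroid genes, 1 of 5 called as lower and 5 adjusted over the list alone, fell as a list (adjusted p = 0.00102; adjusted p = 0.429 with an estimated correlation). Osteoclast genes gave 1 rise and 2 falls among 6 (adjusted over the list alone, 1 and 3; adjusted p = 0.0378; adjusted p = 0.379 with an estimated correlation), with Mmp9 and Acp5 lower and Atp6v0d2 higher. T and NK cell genes, where the highest level was that of Lck at 1.11 CPM, gave 1 rise and 0 falls among 6, the same adjusted over the list alone (camera adjusted p = 0.0458; adjusted p = 0.379 with an estimated correlation). Acp5, the tartrate-resistant phosphatase gene, lost its call in 5 of the 6 fits that left out 1 library (highest adjusted p 0.141, without double knockout replicate 2). The T and NK cell gene that rose was the T cell co-receptor gene Cd8a, from 0.0537 ± 0.00168 to 0.299 ± 0.0724 CPM, near the level of a single fragment in the single knockout and a call lost in each of the 6 fits (highest adjusted p 0.165, without double knockout replicate 2). The osteoclast and the T and NK cell list calls ended without single knockout replicates 2 and 3 and double knockout replicates 1 and 3, with adjusted p values from 0.0587 to 0.0871 for osteoclast genes and from 0.0680 to 0.1599 for T and NK cell genes. Endothelial genes gave 3 rises (Cdh5, Emcn and Egfl7) and 1 fall among 6, the same adjusted over the list alone, without a list call by camera (adjusted p = 0.248), while fry gave the list as higher (adjusted p = 0.0323). The fall was that of the von Willebrand factor gene Vwf, from 67.8 ± 8.603 to 28.7 ± 3.503 CPM. Mesenchymal genes gave 1 rise and 1 fall among 9 (adjusted over the list alone, 4 and 1; adjusted p = 0.4804). Col3a1 fell from 262 ± 22.02 to 151 ± 8.596 CPM and Lum rose from 1.87 ± 0.777 to 5.29 ± 0.477 CPM. Lum lost its call in 4 of the 6 fits that left out 1 library (highest adjusted p 0.0951, without double knockout replicate 2). In the untested lists, 1 of 4 neutrophil genes fell (S100a8, from 5.02 ± 1.01 to 2.38 ± 0.358 CPM, a call lost in 5 of the 6 fits that left out 1 library, with a highest adjusted p of 0.0803 without single knockout replicate 3). Of the others, 0 of 3 dendritic cell, 0 of 2 mast cell, 0 of 2 megakaryocyte and 0 of 4 adipocyte genes passed, with the same counts adjusted over the list alone. None of these had an unadjusted p under 0.05 or was called by DESeq2.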

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

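Counts per fragment, immunoglobulin genes left out, offsets for GC content and limma on log2(FPKM + 1) were tests chosen after the data were seen, and the others were planned. Against 1774 called genes (674 genes higher in the double knockout and 1100 genes lower in the double knockout), DESeq2 called 3733 (1706 higher, 2027 lower), a test against a 1.5-fold change 267 (47 higher, 220 lower), library totals alone 1283 as higher, and limma on log2(FPKM + 1) 1314 as higher and 708 as lower. Leaving out 1 library gave 808 to 1622 called genes, 217 to 698 higher and 591 to 924 lower, and 6 to 11 of the called lists. Of 11 called lists, 7 kept enough members to be tested at a mean of at least 5 CPM and all 7 were called there, while fry called 9 of the 11. With an estimated correlation 0 of the 34 tested lists were called (4 of the 34 had an unadjusted p under 0.05, and fry called 15 of the 34). The test against a 1.5-fold change asks for larger changes by construction, the fits without a library have fewer samples, the filter at 5 CPM left 4 called lists with under 5 members, and for the others the cause was not tested. In all 38 values of the 2 targeted genes, P2ry6 kept its direction and call and Ldlr stayed without a call. Of the values of named genes under alternatives, 2910 kept their side of the threshold, 337 lost the call and 58 gained a call. Among values with a call in either fit, 0 turned direction. For lists the numbers, in the same order, were 425, 36, 7 and 0. Direction was not compared where neither fit gave a call. The lysosome and autophagy list, for example, was lower by camera and higher by fry without a call. Of 128 called named genes, 83 were called in all 6 fits without 1 library. The alternative for files without counts was not run. Depth limits genes near 1 fragment per library, and 1.5-fold changes were mostly missed in the simulated data (22.4% found).

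With the replicate number as a replicate block, 1009 genes were called, with 352 genes higher in the double knockout and 657 genes lower in the double knockout, and 6 lists. Same-numbered libraries did not deviate together (correlations across genes of 0.03, -0.00 and -0.01), so the numbers were not treated as pairs.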

Other observations

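The tests of annotated KEGG and GO terms, of other splits of the libraries, and of the explanations for 3 patterns were all chosen after the results were seen. The hypergeometric test treats genes as independent and takes no account of genes that vary together. The adjusted p values of all terms, higher or lower, may therefore be too small. Of 224 tested genes annotated to angiogenesis 31 were higher, against 9.73 expected (adjusted p = 8.66e-06, hypergeometric test), among them Apln, the gene of the vessel peptide apelin, from 9.65 ± 2.19 to 30.4 ± 3.19 CPM. Of the 31, 22 were highest in replicate 2 among the single knockout libraries. In fits that left out 1 library, 30 of the 224 were higher without single knockout replicate 2 (10.1 expected), and 10 to 16 without any 1 of the other 5 libraries (3.17 to 4.54 expected). The members called higher included the endothelial markers Egfl7, Emcn, Robo4 and Pecam1, and of the 6 endothelial genes of the fixed list Cdh5, Emcn and Egfl7 were higher and Vwf lower in the same libraries. Of 45 genes of the cellular response to interferon-beta 12 were higher (adjusted p = 1.07e-04, hypergeometric test). Among them Ifi204, Ifi209, Ifi211 and Mndal lie together on chromosome 1, from 173630917 to 173913046. Ifi202b, Ifi203, Ifi206 and Ifi207 were also among the 12. The term thus rests in large part on a single gene family, whose members are near-identical and therefore uncertain. The MHC class I peptide loading complex gave 6 of 14 (adjusted p = 0.00209, hypergeometric test), with the peptide transporter gene Tap1 from 24.1 ± 2.04 to 31.97 ± 1.53 CPM. The 6 were Tap1, Tap2, H2-Q4, H2-Q6, H2-Q7 and Calr. All but Calr lie on chromosome 17 between 34187553 and 35443773. The H2-Q genes are close relatives, so the split of reads among them is uncertain. Calr lost its call in 4 of the 6 fits that left out 1 library. The complement and coagulation pathway gave 12 of 55 (adjusted p = 0.00349), with the complement factor B gene Cfb from 5.23 ± 0.458 to 14.3 ± 1.15 CPM. Single genes higher by value were the macrophage genes Cd5l, from 259 ± 18.4 to 427 ± 4.704 CPM, Siglec1, from 86.7 ± 2.57 to 138 ± 7.803 CPM, and Folr2, from 11.4 ± 1.12 to 30.7 ± 3.27 CPM. Folr2 lies 0.865 Mb from P2ry6 on the same chromosome.

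Genes lower in the double knockout included 15 of 45 annotated to positive regulation of phagocytosis (adjusted p = 1.51e-04) and 10 of 22 of amino acid transmembrane transporter activity (adjusted p = 3.85e-04). Symporter activity gave 16 of 69 (adjusted p = 0.00325), with the taurine transporter gene Slc6a6 from 2078 ± 64.8 to 1481 ± 65.1 CPM and the inositol transporter gene Slc5a3 from 165 ± 32.1 to 88.6 ± 7.68 CPM. The C-type lectin receptor genes Clec4n and Clec4e fell from 324 ± 26.1 to 106 ± 10.05 CPM and from 53.1 ± 7.84 to 18.8 ± 2.05 CPM. The NADPH oxidase genes Cybb and Ncf1 fell from 537 ± 34.3 to 338 ± 11.2 CPM and from 302 ± 12.3 to 216 ± 3.56 CPM, and the leukotriene synthesis gene Alox5 from 5.57 ± 0.318 to 1.85 ± 0.272 CPM. Among neighbours of mt-Atp6, mt-Atp8 was at 873 ± 249 and 574 ± 27.9 CPM (adjusted p = 0.114) and mt-Co3 at 2174 ± 771 and 1893 ± 122 CPM (adjusted p = 0.652). Within 0.5 Mb of C5ar1, 1 of 19 genes was called.

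The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1774 genes and the highest of the others 4, so 1 of the 10 splits called as many. Every other split put libraries of both genotypes into each group. Any difference between genotypes then widens the spread within groups and lowers the calls. The count of 4 is thus not a level given by chance, and the splits decide nothing.

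Of the 169 tested genes of the immunoglobulin set, which includes Jchain, 144 were lower in the double knockout. Reads moving between near-identical segments would leave the summed level the same, but the sum over this set was 16.0 times as high in the single knockout (4491 ± 221 against 281 ± 26.3 CPM). Plasma cells, or their RNA, in the single knockout cultures may account for the pattern. The 8 plasma cell transcripts outside the immunoglobulin loci, of which Irf4 and Cd79a are also in other lists, had a median log2 fold change of -2.80. Of the 8, 5 were lower and 0 higher. Jchain went from 133 ± 5.47 to 6.51 ± 0.582 CPM and Mzb1 from 4.599 ± 0.459 to 0.291 ± 0.1596 CPM. Jchain is also among the 169 genes, so its fall is part of the pattern. All of the 8 except Jchain were below 5 CPM in both genotypes. An earlier test of whether the 3 single knockout libraries held one pool of such cells gave a chi-square per degree of freedom of 3.58 over 141 variable segments, decided nothing and was replaced by the summed level. An effect of genotype on such cells stays open and was not tested.

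P2ry6 kept 11.2% of its level in the double knockout, and Arhgef17, which lies downstream on the same strand and begins 5523 bases from it, was higher. Carry-over of single knockout RNA or reads is argued against as the source of the remaining reads, since the median share left over 37 variable segments was 3.91% (quartiles 2.19% to 7.66%). P2ry6 reads counted to Arhgef17 are argued against as the whole cause, since the gain of 176 CPM was 3.14 times the loss of 56.1 CPM, beyond their summed SDs of 8.38 CPM. Strain-derived DNA around the targeted locus cannot be told apart from an effect of genotype: 10 of 142 genes within 5 Mb were called, 7.04% against 9.05% elsewhere with immunoglobulin genes left out (Fisher's exact p = 0.555), and flanking DNA need not change many genes. Transcription from the P2ry6 promoter into Arhgef17 could also raise it and was not tested.

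The orders of the single knockout libraries were read for called genes with an absolute log2 fold change of at least 0.5 and a mean of at least 5 CPM in 1 or both genotypes. Of these, 133 of 267 raised genes (49.8%) were highest in single knockout replicate 2 and lowest in replicate 3, against 47 of 381 fallen genes (12.3%). Over all called genes the shares were 240 of 674 (35.6%) and 97 of 1100 (8.82%). Equally likely orders would give 16.7%, but genes that vary together need not spread evenly over the orders. Of the 381 fallen genes, 108 had replicate 3 highest and replicate 2 lowest. The share of the pattern's order over all tested genes is not given here. A differing share of dividing cells may account for part of the pattern. Of 30 cell cycle genes 28 were highest in replicate 2, as it needs, but 19 had the full order with replicate 3 lowest. Of the 30, 2 were called higher and 1 was among the 133. A later comparison of sizes (median log2 fold change 0.257 against 0.79 in the 133) decides nothing, since the 133 were chosen as raised. Sequencing depth is argued against as the cause of the order in the 133 genes. The estimated counts summed to 58965664, 76768781 and 74856652 in single knockout replicates 1 to 3. An effect that grows or shrinks with depth would place replicate 1, the shallowest, at an end. In the 133 genes replicate 1 lay between replicates 2 and 3, which were close in depth. For the other raised genes depth stays open. Of all raised genes, 58 lay in the order of depth against 44.5 if all orders were equally likely, which decided nothing. Later counts found replicate 1 above the deeper replicate 3 in 133 of 191 and in 183 of 267 raised genes. Both contained the 133 genes of the pattern by definition. Outside them it was 50 of 134, with 84 the other way. Leaving out the 133 removes a whole order with replicate 1 above replicate 3, so this split decides nothing either. RNA from endothelial or mesenchymal cells cannot be told apart from a change in the macrophages, as 4 of 15 markers were higher and 2 lower, and an effect of genotype was not tested.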
